A study of Mus musculus with 2 samples.

How the data were processed

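H3K27ac ChIP-seq peak lists from mouse forebrain at embryonic day 11.5 were analysed: 1 list for each of 2 biological replicates (pools of 109 and 88 embryos), a pooled list and a replicated list. The labels number the replicates and describe separate pools, and both form 1 group. The lists are in the narrowPeak format on the mm10 assembly, per the file headers that accompany them. Per the file headers, each replicate's list was called on its own filtered alignments with control alignments, the pooled list on the alignments of both replicates together, and the replicated list was derived from the pooled list and the replicates' lists. The peak caller, the aligner, their versions and the rule for the replicated list are not given in the sources used here.

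The deposited values are a fold enrichment of ChIP over control per peak, a ratio computed by the authors, and the −log10 of the p-value and of the q-value per peak, also from the authors' peak caller. The lists have no column names, so these meanings rest on the narrowPeak format that the file headers name. The fold ran from 1.29 to 56.6 in the pooled list, and no −log10 p fell below 2.00 in replicate 2 or 2.03 in replicate 1. The deposited lists are permissive: 43.3% of the peaks of replicate 1 and 27.2% of those of replicate 2 had a −log10 q under 2. The distance of the summit from the peak's start is the other value used. Fold values were used to describe, rank or filter peaks within a list. No list gives read counts, so the depth of either library is unknown, and a list of a library with more reads or better enrichment can be longer for that reason. Signal tracks and the control libraries themselves were not used here. There were 0 columns of samples outside the series.

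Genes came from GENCODE release M21 on GRCm38, the assembly also called mm10, and sequence from the RefSeq copy of the same assembly, with chromosomes 1 to 19, X and Y. A start is the 5′ end of any protein-coding transcript of a protein-coding gene, which left 21853 genes. Between 4 and 7 peaks per list lay off these chromosomes and entered no gene comparison. A peak within 1 kb of a start was counted as a promoter peak and any other as distal. A distal peak went to the gene with the nearest start if that lay within 100 kb. Overlaps needed at least 1 bp and were computed with bedtools 2.31.1. Expected values came from 100 seeded placements of peaks of the same widths on the ungapped part of the same chromosome. Spearman's rho was taken over merged regions with peaks of both replicates, on the highest fold of each. Its interval and that of the Jaccard index came from 1000 resamplings of whole chromosomes. Shares have 95% Wilson intervals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

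Before the data were examined, 21 gene lists were fixed with 419 entries, of which 418 were found in the annotation (Olfr151 was not). They cover the dorsal and ventral telencephalon, diencephalon, progenitors, early and mature neurons, glia, midbrain, hindbrain and spinal cord, endothelium, blood, head mesenchyme and neural crest, heart and muscle, liver, limb, pluripotency and germ line, ribosomal proteins, cell cycle, chromatin modifiers, secreted signals, and olfactory and vomeronasal receptors. Promoter peaks in each list were compared with all other genes by a two-sided Fisher's exact test. Distal peaks were compared with 10000 random lists of the same size, matched in 10 bins on the length of sequence nearest to each gene's starts, by a two-sided permutation test. Both were adjusted by the Benjamini-Hochberg method over the 21 lists, with a threshold of 0.05. The comparisons are across genes, and with 2 replicates and no second condition no test across samples was possible. Values for the replicates' own lists are given as mean ± SD with n = 2. Covered bases near a gene are those within 50 kb of any of its starts. Long domains are replicated peaks joined when closer than 12.5 kb, with at least 10 kb covered by peaks.

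Genes were named by a rule fixed beforehand. It takes, per list, the 3 members with the most covered bases of replicated peaks within 50 kb and the first 3 without a promoter peak. It adds the genes of the 15 long domains with the most covered bases, the 10 genes with the highest promoter fold, and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. Members that make up a small count, and the microRNA 9 genes, were named after their values were seen.

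The tests were first tried on simulated data for 21853 genes. Lists planted with promoter peaks in 95% of members were called in 100% of cases, lists planted at 20% in 33% of cases, and unplanted lists in 0.313%. The simulated genes were flagged independently, and unplanted ones at the same rate. The low rate for unplanted lists therefore does not cover effects of promoter CpG content or of neighbours that share peaks. For distal peaks, 2 lists given 3 times the number, over 10 runs, were called in 15% of cases and unplanted lists in 0%. These runs drew fewer random lists than the main test, and their small number gives only a rough rate. Alternatives covered a −log10 q of at least 5, peaks of at least the median fold, stricter overlaps, equal numbers of peaks, promoter windows of 500 bp and 2.5 kb, the gene's 5′ end, random lists matched on promoter CpG content, assignment within 50 or 200 kb, a distal limit of 2.5 kb, covered bases in place of peak numbers, joining within 5 or 25 kb, long domains without promoter peaks, the pooled list, and each replicate's list alone. CpG content was the observed over expected CpG ratio within 500 bp of a start, the highest of a gene's starts. For motifs, 500-bp windows at distal summits were compared with windows 2000 bp to either side, in bins of 2% GC. Flanking windows that lay in a peak or near a start were not left out.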

Results

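Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by ChIP-seq in the forebrain of mouse embryos of the B6NCrl strain at embryonic day 11.5. There was 1 group with 2 biological replicates, each from its own pool of embryos of both sexes: 109 embryos for replicate 1 and 88 for replicate 2. Replicate 1 had 43066 peaks that covered 18.6 Mb, and replicate 2 had 51686 peaks that covered 28.5 Mb. A pooled list, called on both replicates together, held 43090 peaks, and the replicated list held 28123 of these, covering 21.6 Mb. The number of reads behind each list is unknown, so no counting interval could be given for a peak. The design has no second condition. The comparisons are therefore where the mark lay, at which genes, and how far the replicates shared their peaks.

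The mark lay at promoters far more often than randomly placed peaks of the same widths. In the replicated list, 11295 of 28123 peaks (40.2%) came within 1 kb of a protein-coding start, against 3.54% of placed peaks (range 3.25 to 3.84% over 100 placements). The share in the replicates' own lists was 29.7% ± 1.15 (SD, n = 2). Of the replicated peaks, 29.7% lay outside promoters with the summit in an intron (35.9% of placed peaks). For exons it was 2.82% (3.15%) and for intergenic sequence 27.3% (57.4%), also outside promoters. Promoter peaks were set aside first, so the lower intron and exon shares do not show that the mark avoided introns or exons. Promoter peaks were wider than distal peaks, with medians of 613 and 462 bp. They also had a higher median fold enrichment over control, 6.13 against 4.13. These fold values are the authors' own, 1 per peak. Of 21853 protein-coding genes, 9074 (41.5%) had a replicated promoter peak, and the replicates alone marked 41.5% and 47.1%.

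Genes of the telencephalon, of neural progenitors and of newborn neurons carried promoter H3K27ac more often than other genes. All 20 dorsal telencephalon patterning genes had a replicated promoter peak (adjusted p = 1.61e-07, Fisher's exact test), as did all 22 neural progenitor genes (adjusted p = 4.14e-08, Fisher's exact test). In the ventral telencephalon and GABA lineage, 19 of 20 genes had one (adjusted p = 2.81e-06, Fisher's exact test), the exception being Gsx1, a homeobox gene of the ganglionic eminences. Among early postmitotic neuron genes it was 21 of 22 (adjusted p = 6.64e-07, Fisher's exact test), the exception being Neurod6, a bHLH factor of cortical neurons. With only peaks of a −log10 q of at least 5, the shares were 65% for the ventral telencephalon and 77.3% for early postmitotic neurons, and stayed at 100% for the other pair of lists. Msi1, which encodes an RNA-binding protein of neural stem cells, had a promoter fold of 48.2. Nr2f1, an orphan nuclear receptor that patterns the cortex, had 47.8. Foxg1, a forkhead factor needed for telencephalon growth, had 37.4. Sox4 (35.4) and Sox2 (35.3) came next among the genes named for these lists. At Dlx1 and Dlx2, homeobox genes of GABAergic precursors, the values were 10.6 and 6.02, and at Arx 4.83.

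Genes used in every dividing cell were also marked. All 24 ribosomal protein genes (adjusted p = 1.42e-08) and 21 of 23 cell cycle genes (adjusted p = 3.08e-06) had a promoter peak, each by Fisher's exact test. So did 14 of 16 genes for chromatin modifiers of histone H3 lysine 27 (adjusted p = 0.000474, Fisher's exact test). That list covers methylation of this lysine as well as its acetylation. Mcm3 and Bub1 were the cell cycle genes without one, and both had a peak in replicate 2 but not in replicate 1. Ezh1 and Hdac3 were those of the chromatin list, which did not pass against random lists matched on promoter CpG content (87.5% against 71.1%, adjusted p = 0.253, permutation test). Ccnd1, which encodes cyclin D1, had a promoter fold of 22.4, and the bromodomain gene Brd2 had 53.4.

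In 7 lists, promoters carried the mark less often than those of other genes. Of 23 hindbrain and spinal cord genes only Mafb had a replicated promoter peak (adjusted p = 0.000372, Fisher's exact test), and no Hox gene of the list did. Hoxa1, Hoxa2 and Hoxa3 had none in either replicate. Most members of this list are Hox genes, and neighbours such as these lie side by side on a chromosome. The test counts each as independent, so its p-value may be too small. The heart and skeletal muscle list had 1 of 20, Myh7 (adjusted p = 0.000868, Fisher's exact test), with Nkx2-5, Gata4 and Hand2 unmarked. The liver list had Trf and Hhex of 20 (adjusted p = 0.00796, Fisher's exact test), and Alb and Afp had no peak within 50 kb in either replicate. Of the pluripotency and germ line genes, Klf4 was the 1 of 18 (adjusted p = 0.00234, Fisher's exact test), while Pou5f1, Nanog and Zfp42 had none. Of the olfactory and vomeronasal receptor genes it was Vmn1r4, 1 of 17 (adjusted p = 0.00373, Fisher's exact test). No blood gene of 18 had one (adjusted p = 0.000323, Fisher's exact test), and the endothelium list had 3 of 18, Cldn5, Egfl7 and Fli1 (adjusted p = 0.0492, Fisher's exact test). Against random lists matched on promoter CpG content, the liver list (10% against 17.5%, adjusted p = 0.605), the olfactory and vomeronasal receptor list (5.88% against 6.60%, adjusted p = 1), the blood list (0% against 4.95%, adjusted p = 0.861) and the endothelium list (16.7% against 32.7%, adjusted p = 0.223) did not pass, each by the permutation test. The blood and endothelium results also depended on the peak list used. Replicate 2 alone marked 6 of 18 blood genes, among them Hbb-bh1, Klf1, Gypa, Slc4a1, Cd68 and Aif1 (adjusted p = 0.382, Fisher's exact test). In replicate 2 the promoter fold was 2.94 at Hbb-bh1, 4.18 at Slc4a1, 3.13 at Cd68 and 2.79 at Aif1. Replicate 1 marked 2 blood genes, Klf1 and Csf1r. Endothelial genes with a peak numbered 5 in replicate 1 (adjusted p = 0.396) and 6 in replicate 2 (adjusted p = 0.382), neither past the threshold by Fisher's exact test.

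**Figure D1:**
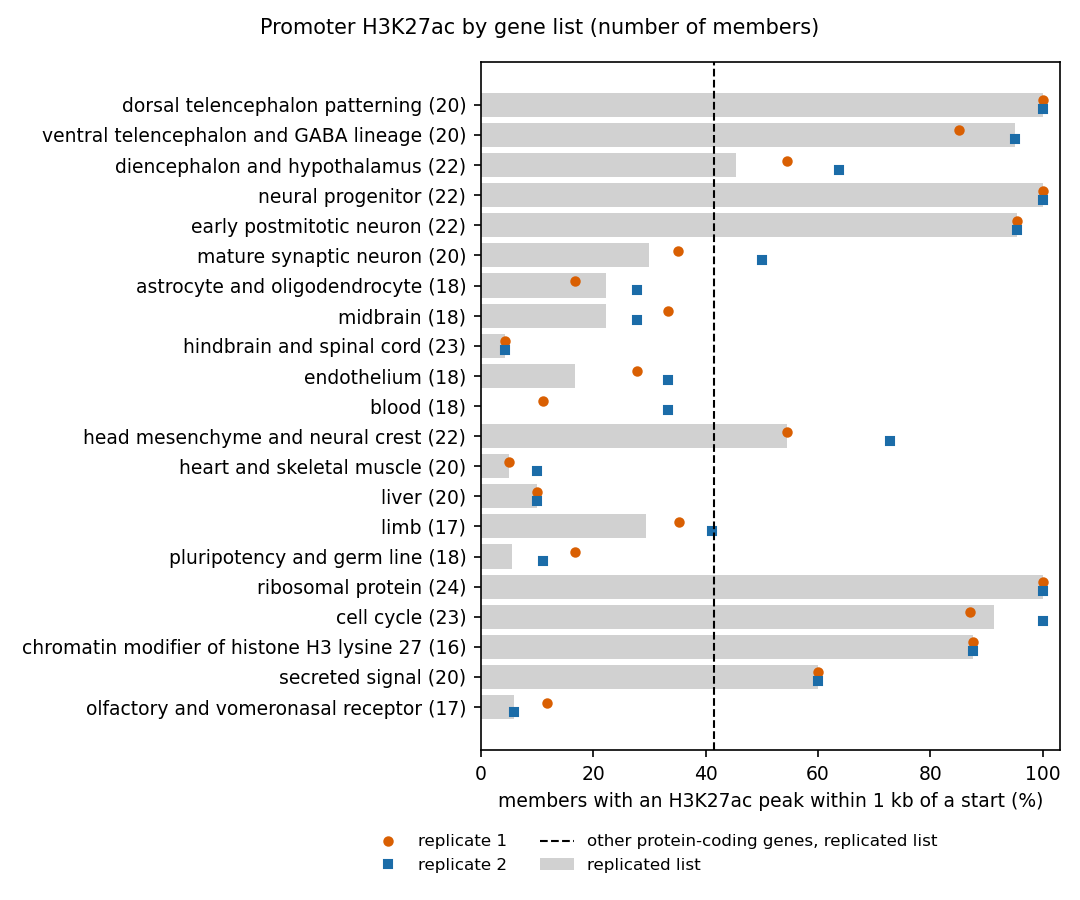
Share of each gene list's members with an H3K27ac peak within 1 kb of a start, in percent. Grey bars show the replicated list, orange circles replicate 1, blue squares replicate 2, and the dashed line other protein-coding genes. The dorsal telencephalon, neural progenitor and ribosomal protein lists reach 100%, and the hindbrain and spinal cord list stays at 4.35% in each.

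The remaining 7 lists did not pass the test. Diencephalon and hypothalamus genes had a promoter peak in 10 of 22 cases (adjusted p = 0.829, Fisher's exact test). The replicates' own lists marked 12 (replicate 1) and 14 (replicate 2) of the 22. Zic1 and Zic4 (fold 17.8, 1 shared peak) and Zic2 (22.3) were marked, and Barhl1 and Gbx2 were not in either replicate. Lhx1 had no replicated promoter peak, but a weak peak in replicate 1 (fold 3.58) and in replicate 2 (fold 3.28). Midbrain genes had 4 of 18, Lmx1a, Nr4a2, Tal1 and Fgf17 (adjusted p = 0.184, Fisher's exact test), and the engrailed genes En1 and En2 had no peak within 50 kb in either replicate. Pax2 had a promoter peak in replicate 1 only (fold 3.09). Mature synaptic neuron genes had 6 of 20 (adjusted p = 0.406) and astrocyte and oligodendrocyte genes 4 of 18 (adjusted p = 0.184), both by Fisher's exact test. Vamp2 and Slc17a6 of the first list and Slc1a2 and Mobp of the second were marked, while Grin2a, Grin2b, Gfap and Aqp4 were not. Snap25 of the first list had a promoter peak in replicate 2 only (fold 2.94). The replicates' own lists marked 7 (replicate 1) and 10 (replicate 2) of the 20 mature synaptic neuron genes. Limb genes had 5 of 17, Alx4, Lhx9, Sall4, Meis1 and Meis2 (adjusted p = 0.484, Fisher's exact test). Secreted signals had 12 of 20 (adjusted p = 0.158, Fisher's exact test), with Wnt8b, Wnt7b and Fgf15 marked and Shh, Wnt1 and Wnt2b unmarked. Head mesenchyme and neural crest genes had 12 of 22 (adjusted p = 0.325), but 16 of 22 in replicate 2 alone (adjusted p = 0.0294) and 81.8% in the pooled list (adjusted p = 0.0018), each by Fisher's exact test. The astrocyte and oligodendrocyte list passed in replicate 1 alone with 3 of 18 (adjusted p = 0.0491, Fisher's exact test). Genes were treated as independent, although neighbours such as Dlx1 and Dlx2 can share peaks and some genes are in 2 lists.

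Distal peaks gathered at forebrain regulators as well. Of 16828 replicated peaks over 1 kb from every start, 12922 (76.8%) had their nearest start within 100 kb, and 4637 genes had at least 1. Dorsal telencephalon genes had a mean of 8.65 such peaks, against 1.31 in random lists matched on the length of sequence nearest to each gene (adjusted p = 0.0021, permutation test). Neural progenitor genes had 6.55 against 0.959 (adjusted p = 0.0021, permutation test). For the ventral telencephalon it was 5.35 against 0.976 (adjusted p = 0.0028), for early postmitotic neurons 4.00 against 1.20 (adjusted p = 0.0189), and for the diencephalon and hypothalamus 3.50 against 1.16 (adjusted p = 0.0395), each by the permutation test. All 5 also passed in each replicate alone, but with covered bases in place of peak numbers the diencephalon (adjusted p = 0.0689) and early postmitotic neuron lists (adjusted p = 0.0598) did not, nor did the diencephalon list at a −log10 q of at least 5 (adjusted p = 0.0512), each by the permutation test. In the replicates' own lists the dorsal telencephalon mean was 14.0 ± 0.530 and the progenitor mean 10.5 ± 0.900 (SD, n = 2). Sox2 had 20 distal peaks, Nr2f1 20 (29.5 ± 10.6 in the replicates, SD, n = 2) and Nr2f2 19 (27.5 ± 2.12). Arx had 14, Dlx2 11 and Lhx5, a homeobox gene of Cajal-Retzius cells, 10. Lhx5 is in both the early postmitotic neuron and the diencephalon and hypothalamus lists, and Zic4 of the latter had 19. The mean of the diencephalon and hypothalamus list thus rests in good part on few genes.

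The other 16 lists did not pass against matched genes in the replicated list. No list had fewer distal peaks with an adjusted p under 0.05, nor with an unadjusted permutation p under 0.05 (0 lists). Secreted signal genes had 1.95 against 0.846 (adjusted p = 0.191, permutation test). Hindbrain and spinal cord genes had 0.087 against 0.248 (adjusted p = 0.825, permutation test). Olfactory and vomeronasal receptor genes had 0 peaks against 0.435 (adjusted p = 0.191, permutation test). They passed as fewer in the pooled list (adjusted p = 0.0483), in replicate 1 (adjusted p = 0.0161) and in replicate 2 (adjusted p = 0.0182), each by the permutation test. In 10 simulated runs with 2 lists of 3 times the usual number, this test with fewer random lists called 15%. That rate is rough, and lists that did not pass may still differ.

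**Figure D2:**
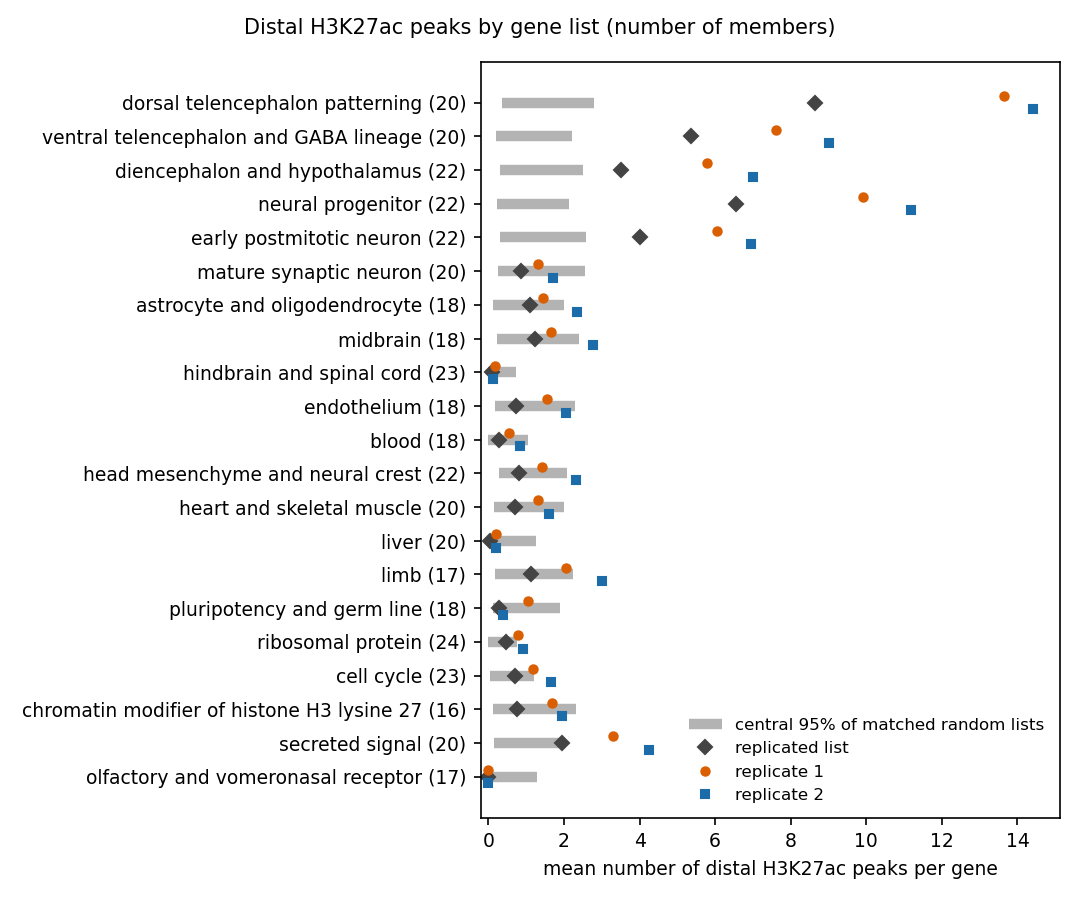
Mean number of distal H3K27ac peaks per gene in each list. Black diamonds show the replicated list, orange circles replicate 1, blue squares replicate 2, and grey bars the central 95% of matched random lists for the replicated list. The replicates' own lists hold more peaks in all, so their points lie to the right of the diamonds except for the olfactory and vomeronasal receptor list, where all are 0, and the dorsal telencephalon list lies farthest right at 8.65.

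Long stretches of the mark lay over a small set of genes. After nearby peaks were joined, 133 of 14811 domains had at least 10 kb covered by peaks, and they held 10.1% of all covered bases. A protein-coding start lay inside 101 of them, of 194 genes (0.888% of all). Of the dorsal telencephalon list, 8 of 20 genes started inside one: Emx2, Pax6, Lhx2, Foxg1, Nr2f1, Nr2f2, Dmrta2 and Fezf2. Of the neural progenitor list it was 9 of 22, among them Sox1, Sox2, Nes, Hes5 and Notch1. Of the ventral telencephalon list it was 6 of 20, among them Dlx1, Dlx2, Six3 and Otx2. The diencephalon list had 3 (Zic1, Zic2 and Zic4), the chromatin list 1 (Kdm6b), and the other 16 lists 0. The number of long domains differed between the replicates, 92 in replicate 1 and 230 in replicate 2.

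The domain with the most covered bases lay on chromosome 7 from 79495650 to 79558806 (mm10), with 52.3 kb covered (51.2 ± 2.45 kb in the replicates, SD, n = 2). No protein-coding gene starts in it, and the nearest start is that of Polg. It contains the noncoding genes Mir9-3hg and Mir9-3, named here after the values were seen. The second lay across Gse1 on chromosome 8 (120399916 to 120566228), with 50.9 kb covered, and Gse1 had more distal peaks than any other gene, 62. The third covered 50.3 kb on chromosome 2 around 1700001O22Rik and Ntmt1. This order holds for the replicated list. Peaks of replicate 2 covered more of the third domain (56.8 kb) and the second (56.4 kb) than of the first (53.0 kb). The fourth, on chromosome 3 with 44.7 kb covered, had its nearest protein-coding start at Rhbg. Then came domains at Zic1 and Zic4 (39.7 kb), Nr2f2 (39.4 kb) and Nr2f1 (39.0 kb). A cluster of 14 histone genes on chromosome 13, from Hist1h4h to Hist1h4d, had 35.8 kb. They belong to several histone families, whose members are similar in sequence, and how reads were placed among them is not given in the sources used here. Sox2 had 32.8 kb (chromosome 3, 34637112 to 34692706). A domain on chromosome 13 with Mef2c as its nearest coding start had 32.2 kb. The next were those at A930004D18Rik, Mllt10 and Skida1 (29.8 kb), Src (28.9 kb), Trak1 (28.7 kb), Bahcc1 (28.3 kb), and Foxg1 and Gm43517 (25.6 kb).

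**Figure D3:**
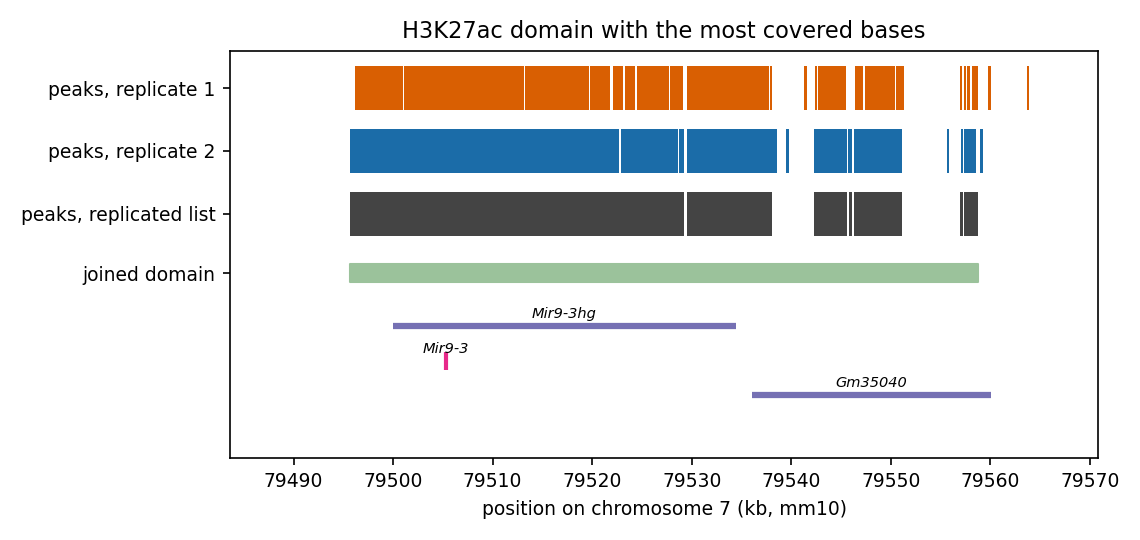
Map of the domain with the most covered bases, on chromosome 7 (position in kb, mm10). Rows show the peaks of replicate 1 (orange), replicate 2 (blue) and the replicated list (black), the joined domain (green), and annotated noncoding genes, long ones in purple and the microRNA gene in pink. Inside the domain lie 22 peaks of replicate 1, 11 of replicate 2 and 7 of the replicated list, so the same stretch was cut into more peaks in replicate 1.

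In the replicated list, the promoter peak of highest fold, 56.6, was that of Tnrc18, a gene on chromosome 5 from 142724661 to 142817662. It was followed by Kansl1, part of a histone acetyltransferase complex (54.5), Dyrk1a, a kinase gene (54.1), Setd1b, a histone H3 lysine 4 methyltransferase gene (54.0), and the transcription factor gene Sp3 (53.7). Brd2 and its neighbour H2-DMa shared a peak of 53.4, and Gm10762 and Zc3h6 shared a peak of 50.8. A peak of 50.4 lay at an annotated start of Agrp, whose gene model runs from 105566698 to 105637393 on the minus strand of chromosome 8. Whether this peak belongs to Agrp or to another gene that starts nearby was not tested. All 10 genes had a promoter peak in each replicate, but their order differed. Sp3 was above Tnrc18 in replicate 1 (44.1 and 37.2) and in replicate 2 (56.4 and 51.8), and Setd1b was the lowest of the 10 in replicate 1 (27.4).

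On the sex chromosomes, which embryos of both sexes contributed, the mark was sparse. The X chromosome held 626 replicated peaks, or 3.83 per Mb, and 25.8% of its genes had a promoter peak. Chromosome 1 held 9.12 per Mb, and the autosomes ranged from 8.68 (chromosome 3) to 18.8 (chromosome 11). The copy number and mappability of the sex chromosomes were not accounted for. Xist, the RNA that silences the inactive X chromosome, had 1 peak at its start in the replicated list (fold 3.95) and in replicate 2 (fold 5.35), and none in replicate 1. The Y chromosome held 4 peaks in replicate 1, 1 in replicate 2, 3 in the pooled list and 0 in the replicated list. Uty had 1 peak at its start in replicate 1 and 2 in the pooled list, while Ddx3y, Eif2s3y and Kdm5d had none in any list.

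Strong peaks overlapped between the replicates more often than weak ones. Of the peaks of replicate 1, 27787 of 43066 (64.5%, 95% Wilson interval 64.1 to 65.0) overlapped a peak of replicate 2 by at least 1 bp, against 1.95% of placed peaks. Of the peaks of replicate 2, 22997 of 51686 (44.5%, interval 44.1 to 44.9) overlapped replicate 1, against 1.58%. With each list ranked by fold and split into 10 equal parts, 99.6% and 99.9% of the strongest part overlapped, and 38.8% and 13.4% of the weakest. Promoter peaks overlapped in 88.2% and 67.8% of cases, and distal peaks in 54.2% and 35.0%. The Wilson intervals cover counting error only and treat peaks as independent. The replicates shared 13.8 of 33.3 Mb, a Jaccard index of 0.414 (95% interval over resampled chromosomes 0.407 to 0.421). Across 21368 shared regions, which are not independent replicates, Spearman's rho of the fold values was 0.768 (0.760 to 0.776).

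**Figure D4:**
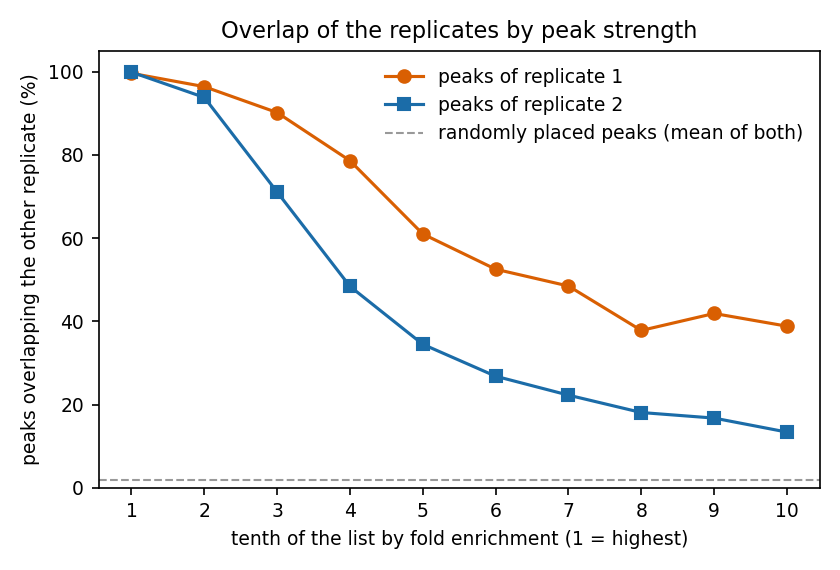
Share of peaks that overlap the other replicate, in percent, for 10 equal parts of each list ranked on fold enrichment (1 is the highest). Orange circles show peaks of replicate 1, blue squares those of replicate 2, and the dashed line randomly placed peaks. Both lines start near 100%, and they end at 38.8% and 13.4%.

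The replicated list kept 28123 of the 43090 pooled peaks (65.3%, 95% Wilson interval 64.8 to 65.7), with identical positions. Of promoter peaks 80.8% were kept, and of distal peaks 57.8%. The kept peaks had a median width of 516 bp and a median fold of 4.62. The 14967 left out had 220 bp and 3.05, and 17.9% of them lay at promoters. Of the kept peaks, 81.7% overlapped a peak of replicate 1, 96.6% one of replicate 2, 78.6% both, and 79 peaks neither. Being in the replicated list is therefore not the same as overlapping a peak in both replicates' own lists.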

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

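Overlap between the replicates moved with every setting tried, and the cause was not tested. Peaks per replicate averaged 47376, and 14216 with a −log10 q of at least 5 or 24340 with at least the median fold, by construction. The share of replicate 1 peaks overlapped by replicate 2 was 58.0% for an overlap of at least 0.5 of the peak, 30.7% for 0.5 of both peaks, 92.2% at a −log10 q of at least 5, 78.1% at the median fold and 62.1% with equal numbers. The share of replicate 2 peaks overlapped by replicate 1 was 27.6%, 25.5%, 53.3%, 52.7% and 50.4% under the same settings. The Jaccard index was 0.487 at the stricter q, 0.480 at the median fold and 0.435 with equal numbers. Spearman's rho was 0.787 at the stricter q, 0.633 for distal regions and 0.783 with −log10 p ranked. The pooled peaks kept were 99.2% at the stricter q and 64.3% at the median fold. In the latter, each list was cut at its own median, 3.75 for the pooled and 4.62 for the replicated list. The 64.3% is limited by these unequal cuts and does not show how many of the stronger pooled peaks were kept.

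The promoter share was 37.9% with 500 bp, 44.3% with 2.5 kb, 34.4% with the gene's 5′ end, 52.5% at the stricter q, 32.4% in the pooled list, and 28.8 to 30.5% with either replicate's list alone. Long domains numbered 68 when joined within 5 kb, 226 within 25 kb, 66 without promoter peaks, 86 at the stricter q, and 92 to 230 with either replicate alone.

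The count of lists with another promoter share, 14, was 11 to 15 in all 8 alternatives. With lists matched on CpG content 5 calls were lost (blood, endothelium, liver, olfactory and vomeronasal receptors, and chromatin modifiers) and 2 gained (midbrain and limb). Midbrain was also gained at the stricter q, head mesenchyme in the pooled list and with replicate 2 alone, and the astrocyte and oligodendrocyte list with replicate 1 alone. Endothelium lost its call in 5 of the 8, and blood also with replicate 2 alone. Distal calls numbered 5, and 4 at the stricter q, 6 in the pooled list and with either replicate alone, where the olfactory list was gained as fewer, and 3 with covered bases. With covered bases the diencephalon list had an adjusted p of 0.0689 and the early neuron list one of 0.0598 (permutation test), and the diencephalon list had 0.0512 at the stricter q (permutation test). Over the 8 alternatives their values ran from 0.00252 to 0.0689 and from 0.00105 to 0.0598 (permutation test). No list's call changed direction. Depth could not be matched, since no list gives reads.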

Other observations

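The tests of the replicates' difference, of the 3 lists named below for CpG content, and the look at microRNA 9 were chosen after the values were seen. The other tests were set before they were run. The bounds for promoter CpG content are worded on the 7 higher and 7 lower lists, so they followed the promoter results. All 3 mouse genes for microRNA 9, a microRNA abundant in the developing brain, lay inside domains among the 10 with the most covered bases. Mir9-3 (chromosome 7, 79505264 to 79505353) lay in the first, Mir9-1 (chromosome 3, 88215598 to 88215686) in the fourth, and Mir9-2 (chromosome 13, 83738814 to 83738885) in the tenth. The protein-coding genes nearest to these domains, Polg, Rhbg and Mef2c, do not start inside them. Covered lengths in the replicates were 51.2 ± 2.45, 43.0 ± 3.47 and 31.5 ± 2.46 kb (SD, n = 2).

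Whether distal peaks carry sites of the factors named in the forebrain lists was tested at 16822 distal summits (49.3% GC) against 33641 flanking windows (46.1% GC), which were weighted to the peaks' GC content in bins. Some flanking windows may themselves lie in peaks, so the ratios do not compare peaks with unmarked sequence alone. Homeodomain sites (TAATTA) were 1.55 times as dense in peaks (95% interval over chromosomes 1.48 to 1.62), SOX sites (ACAAWG) 1.34 times (1.31 to 1.38) and proneural E-boxes (CAGMTG) 1.12 times (1.09 to 1.14). These 3 motifs, named beforehand for the test, passed its bound of 1.1, but the other forebrain motifs did not (RFX 1.06, NFI 1.05 and TEAD 1.05), and without the weighting the homeodomain ratio was 1.09, under the bound. A shuffled SOX site gave 1.00 (0.982 to 1.02), but the shuffled homeodomain site, which still holds the ATTA core, gave 1.32 (1.24 to 1.39, and 0.905 unweighted), so it is a weak control and AT-rich words in general may add to the excess. Motifs of other tissues came close to the E-box ratio or above it (GATA 1.08, 1.04 to 1.13, and MEF2 1.16, 0.935 to 1.38), and no binding was measured.

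Against random lists matched on promoter CpG content, midbrain genes (22.2% against 58.6%, adjusted p = 0.00252) and limb genes (29.4% against 63.1%, adjusted p = 0.0135) also had fewer promoter peaks, each by the permutation test. Neither had passed against all other genes with all replicated peaks, but midbrain genes did with peaks of a −log10 q of at least 5 (5.56%, adjusted p = 0.0147, Fisher's exact test).

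The first pattern weighed is that 7 lists had promoter peaks more often and 7 less often than other genes, since CpG-rich promoters carry H3K27ac more often in general. Promoter CpG content as the whole cause is argued against for the higher lists: 6 of the 7 still passed against random lists matched on it (permutation test), and the chromatin modifiers did not (87.5% against 71.1%, adjusted p = 0.253, permutation test). For the 7 lower lists, 3 still passed. This is fewer than the 4 set, before the matched test was run, as evidence against promoter CpG content, so for the set it stays open. Hindbrain and spinal cord (4.35% against 54.1%), pluripotency and germ line (5.56% against 46.2%) and heart and skeletal muscle (5% against 28.3%) remained lower, the highest adjusted p being 0.0189 (permutation test). The random lists did not copy the neighbouring Hox genes of the hindbrain and spinal cord list, so the p-value of that list may be too small. Blood and olfactory genes could hardly pass, because their matched lists had only 4.95% and 6.60%, and no biological explanation was tested.

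The second pattern is that replicate 2 covered 1.53 times as many bases as replicate 1. Of regions with a fold over 10 in either replicate, at most 0.123% had no peak in the other, but nearly all strong peaks were already known to be shared, so this decides nothing about a more sensitive library of the same chromatin. That and more cells of neighbouring tissues or blood in one replicate cannot be told apart, since no list gives reads and lists of both kinds of cells moved, and no biological explanation was tested. Log2 ratios of replicate 2 over replicate 1 were taken per gene, with 500 bp added to both values, and averaged over each list. Of 5 lists for such cells 1 differed from genes matched on covered bases, that for head mesenchyme and neural crest. It had a mean of 1.04 kb per gene in replicate 1 and 2.06 kb in replicate 2. Its mean log2 ratio was 0.79, against 0.39 in matched genes (adjusted p = 0.0084, permutation test). The same held for early postmitotic neurons (0.71 against 0.47) and the ventral telencephalon (0.68 against 0.46), which belong to the tissue, and pluripotency and germ line genes went the other way (-0.16 against 0.24).

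Within the head mesenchyme list, bases near Col1a2 went from 415 in replicate 1 to 3482 in replicate 2, near Pdgfra from 604 to 2301, and near Twist1 from 0 to 1407 (within 50 kb of a start), genes picked after their values were seen. Of its 22 members, 19 had more covered bases in replicate 2 and 3 had more in replicate 1. Such a tally was not particular to this list. More bases in replicate 2 were also seen for 22 of 22 early postmitotic neuron, 20 of 20 dorsal telencephalon and 23 of 24 ribosomal protein genes. In the pluripotency and germ line list, 5 members had more in replicate 2 and 9 had more in replicate 1. The blood list did not pass against matched genes (0.57 against 0.41, adjusted p = 0.354, permutation test). Of its members, 13 had more covered bases in replicate 2 and 4 had more in replicate 1. The embryonic globin gene Hbb-bh1, 1 member, had 380 covered bases nearby in replicate 1 and 1966 in replicate 2.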
